A study of Homo sapiens with 64 samples.

How the data were processed

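Bulk RNA was measured in 64 diagnostic liver biopsies, stored frozen, from paediatric patients with autoimmune liver disease. Per the labels, 30 libraries belong to the AIH group (autoimmune hepatitis), 17 to PSC (primary sclerosing cholangitis) and 17 to ASC, a label that the sources used here do not spell out and that usually stands for autoimmune sclerosing cholangitis. The description of the series counts 34 PSC biopsies against 30 AIH biopsies, so the 34 hold the PSC and ASC labels together. RNA was isolated with a miRNeasy kit and sequenced as 100 bp paired-end reads to a stated depth of 50 M reads (M, mega). Per the submitters' processing notes, reads were aligned to GRCh38 with STAR 2.7.2b and counted per gene with featureCounts 1.6.4. The annotation release, the strand setting and the treatment of mates, multi-mapped reads and overlapping genes are not given in the sources used here.

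The deposited table holds whole-number read counts, not normalised, for 41096 gene symbols, of which 998 had no count in any library. Library totals ran from 40.16 to 350.2 M counts with a median of 143.1 M, and 63 of 64 totals lay above the stated depth. Of 20261 genes with over 500 counts in over 30 libraries, 21 held only multiples of one number above 1 in every library, so a count is not always a distinct fragment. The antisense gene A1BG-AS1 held a median of 21.0% of the counts of A1BG (range 11.5 to 28.4%). No libraries were identical. Counting errors were therefore left to the spread between libraries, which the tests below estimate, and no interval was computed from a count alone. Positions come from RefSeq annotation of GRCh38, matched by symbol for 40517 of the genes; the deposited table itself gives no positions.

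Genes on the Y chromosome, XIST, TSIX and related sex-linked transcripts (432 genes) were left out of every test. The main test was the quasi-likelihood F test of edgeR 4.0.16 (robust fit, TMM factors, filterByExpr on the groups) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The pooled comparison (PSC and ASC together against AIH) used a fit with 2 groups, and PSC against AIH, ASC against AIH and PSC against ASC used one fit with 3 groups. Adjusted p values for genes are from edgeR quasi-likelihood unless another tool is named. No covariate entered these fits. Log2 fold changes carry their standard error. CPM values are counts scaled to a common library total, without TMM factors. Log2 CPM values, used for list means and correlations, include TMM factors.

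A total of 42 gene lists covering the cells of the liver and of blood, bile acid and hepatocyte functions, immune responses, matrix, growth and stress was fixed in advance. Each list was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the 42 lists. The same lists were tested with a correlation estimated per list, with fry, which asks whether the genes of a list move one way on balance, and by a two-sided permutation test of the mean log2 CPM (prior count 2) per library. Members were counted with adjustment over all genes and over the list alone. List medians are medians of the members' log2 fold changes.

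The rule for naming genes was as follows. For the pooled comparison it took the 6 largest increases and 6 largest decreases past an adjusted p of 0.05 with a mean CPM of at least 1, and the 4 smallest p in each direction. For every other comparison it took the 4 largest changes in each direction. For each list described it took up to 4 tested members with the smallest p. KRT7, KRT19, ALB, CYP7A1, ABCB11, SLC51B, COL1A1, CXCL9, CD8A and IGHG1 were named whatever their p. Immunoglobulin and T cell receptor segments and pseudogenes were tested and not named, and 2 other genes that the rule takes are not reported here. The groups, the comparisons, the tests, the lists, this rule and the alternatives listed first below were chosen before the data were examined.

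The alternatives tried were RLE and upper-quartile factors, DESeq2 1.42.0, limma voom with quality weights, no low-count filter, a minimum CPM of 1 in 17 libraries, the run of library numbers as a factor, the mean of 6 pan-leukocyte genes or of the cholangiocyte list as a covariate, exclusion of immunoglobulin, T cell receptor and haemoglobin genes, another grouping of the samples and a minimum absolute log2 fold change of 1. Further ones, chosen after seeing the data, were a fit without 1 ASC library that held placental transcripts, a fit without the 6 libraries whose median correlation with the others was under 0.97, leaving out each of the 64 libraries in turn, and the permutation test of list means, with and without covariates. The library numbers were cut into 4 runs, which hold 14, 11, 25 and 14 libraries. Every value within runs refers to them in that order. The run of 25 includes a separate stretch of numbers that holds PSC and ASC libraries and no AIH library.

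Library measures, list means and correlations were tested by two-sided permutation (100000 resamples, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). The smallest p these permutations can give is 1e-05. Correlations of gene pairs, and the search they came from, were chosen after the data were seen; the difference of r between groups was tested by permuting group labels on values centred and scaled within each group. That test was first run on uncentred values and replaced because the groups differ in mean. Differences with a covariate permuted the residuals of the model without the group. On counts simulated from these libraries with 200 of 20300 genes changed, the pooled edgeR test called 80% of genes changed 2-fold and 93% of genes changed 4-fold, with 4.62% false calls. The same shares were 74%, 92% and 5.52% for PSC against AIH, 59%, 88% and 4.40% for ASC against AIH, and 68%, 89% and 4.71% for PSC against ASC. The genes of the T cell list were lowered as well in these simulations. Counts were drawn independently for each gene, so no library was extreme over many genes at once. The shares of false calls therefore need not hold for the real libraries, where random splits called a median of 7 genes in the pooled comparison (highest 192). Age, sex, treatment and histology were not used here.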

Results

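Gene expression was measured once in each of 64 liver biopsies: 30 AIH, 17 PSC and 17 ASC. The median library total was 138.3 M counts (M, mega) in AIH (range 70.16 to 350.2), 159.0 M in PSC (40.16 to 336.5) and 140.2 M in ASC (77.15 to 333.4). The pooled mean was 167 M in PSC and ASC together and 149 M in AIH, a difference that permutation did not separate from 0 (p = 0.296, adjusted p = 0.507 over 6 measures). The number of genes detected, the share of the 10 most abundant genes and the shares of mitochondrial, immunoglobulin and erythrocyte transcripts gave adjusted permutation p values of 0.484 or more between PSC and ASC together and AIH, and of 0.823 or more between PSC and ASC. Immunoglobulin transcripts took 0.0306% of counts in PSC and ASC together (SD 0.0489, n = 34) and 0.0568% in AIH (SD 0.0688, n = 30), permutation p = 0.0807. The mean of 6 pan-leukocyte genes was 4.07 log2 CPM in PSC and ASC together and 4.41 in AIH (permutation p = 0.0603). The 4 runs of library numbers held 4, 6, 13 and 7 AIH libraries, 6, 1, 7 and 3 ASC libraries and 4, 4, 5 and 4 PSC libraries, and their median totals were 270.0, 146.2, 133.6 and 130.1 M.

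The pooled comparison asked how the liver in sclerosing cholangitis, under the PSC and ASC labels, differed from the liver in autoimmune hepatitis. FGGY, which encodes a carbohydrate kinase (chromosome 1, 59296378 to 59762730), rose 1.98-fold in PSC and ASC together, with a log2 fold change of 0.99 ± 0.18 (SE, n = 34 and 30, adjusted p = 0.00543). Its median was 51.1 CPM against 32.9 CPM, and 27 of the 34 libraries lay above the AIH median. DBNDD1 (chromosome 16, 90004871 to 90019890), a gene of little-known function, rose 4.25-fold (log2 2.09 ± 0.38, adjusted p = 0.00394, medians 7.10 and 3.65 CPM, higher in 26 of 34 libraries). PLEK2, a pleckstrin-family protein of the actin cytoskeleton (chromosome 14, 67386984 to 67412165), fell by 0.84 ± 0.17 on the log2 scale (adjusted p = 0.0114, medians 4.66 and 7.49 CPM, lower in 30 of 34 libraries). HLA-DQA2, a little-expressed HLA class II alpha chain gene (chromosome 6, 32741391 to 32747198), fell by 2.30 ± 0.46 (adjusted p = 0.0114, medians 0.583 and 2.97 CPM, lower in 31 of 34 libraries). Random splits of the libraries also gave calls, at least 2 in each of 99, so these adjusted p values may be too small.

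Among 19282 genes tested with edgeR, 35 passed an adjusted p of 0.05, 23 higher and 12 lower, and 28 of them had an absolute log2 fold change of at least 1. With the run of library numbers as a factor edgeR called 4, 2 higher and 2 lower, with 1585 at an unadjusted p under 0.05. DESeq2 called 27 higher and 39 lower, 17 of them shared with edgeR, and limma voom 23 higher and 40 lower, 8 of them shared, so the balance of directions depended on the tool. At an unadjusted p under 0.05 there were 1684 genes in the main test, where 964.1 would be expected without any difference. Genes are not independent, and the spread of this count without a difference was not determined. FGGY, PLEK2, DBNDD1, HLA-DQA2 and CCDC187 (log2 3.48 ± 0.71, adjusted p = 0.0114, medians 0.142 and 0.081 CPM, higher in 23 of 34 libraries) kept their calls when any 1 of the 64 libraries was left out, as did FGF12 and LINC01447, 2 called genes that the naming rule does not include. FGGY differed by log2 0.99, 0.81, 1.21 and 0.49 within the 4 runs, PLEK2 by -0.41 to -1.03, and HLA-DQA2 by -2.40, -1.70, -2.65 and -1.63. DBNDD1 differed by 3.16, 0.93 and 2.30 in runs 1 to 3 and by -0.74 in run 4, and CXCL11 by 0.28, -1.69, -2.34 and -1.48. Over 13 alternative settings FGGY and PLEK2 were called in 13, and DBNDD1 and HLA-DQA2 in 11. With the run as a factor DBNDD1 was at 1.54 ± 0.40 (adjusted p = 0.201), HLA-DQA2 at -2.20 ± 0.47 (adjusted p = 0.0533) and CCDC187 at 2.95 ± 0.83 (adjusted p = 0.234). With the leukocyte covariate HLA-DQA2 was at -1.46 ± 0.45 (adjusted p = 0.348) and CCDC187 at 3.23 ± 0.78 (adjusted p = 0.104). Within runs the number of called genes was 0, 0, 10 and 0 (edgeR, with 1671, 1139, 2871 and 727 genes at an unadjusted p under 0.05). The total of 35 became 14 without 1 ASC library, 23 without either of 2 AIH libraries and 117 without 1 PSC library. In the 64 fits CD8A, ICOS, HLA-DRA, HLA-DOB, HLA-DPA1, CTLA4 and TIGIT, uncalled in the main fit, were each called in 1. FOXP3, GZMK and IGHA1 were called in 0. The counts of 0 over all genes given below for immune lists therefore depend partly on the libraries in the fit. The T cell list mean was 2.22 log2 CPM in 1 PSC library and 1.005 in the next highest PSC library. Which library gave those calls was not examined.

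**Figure D1:**
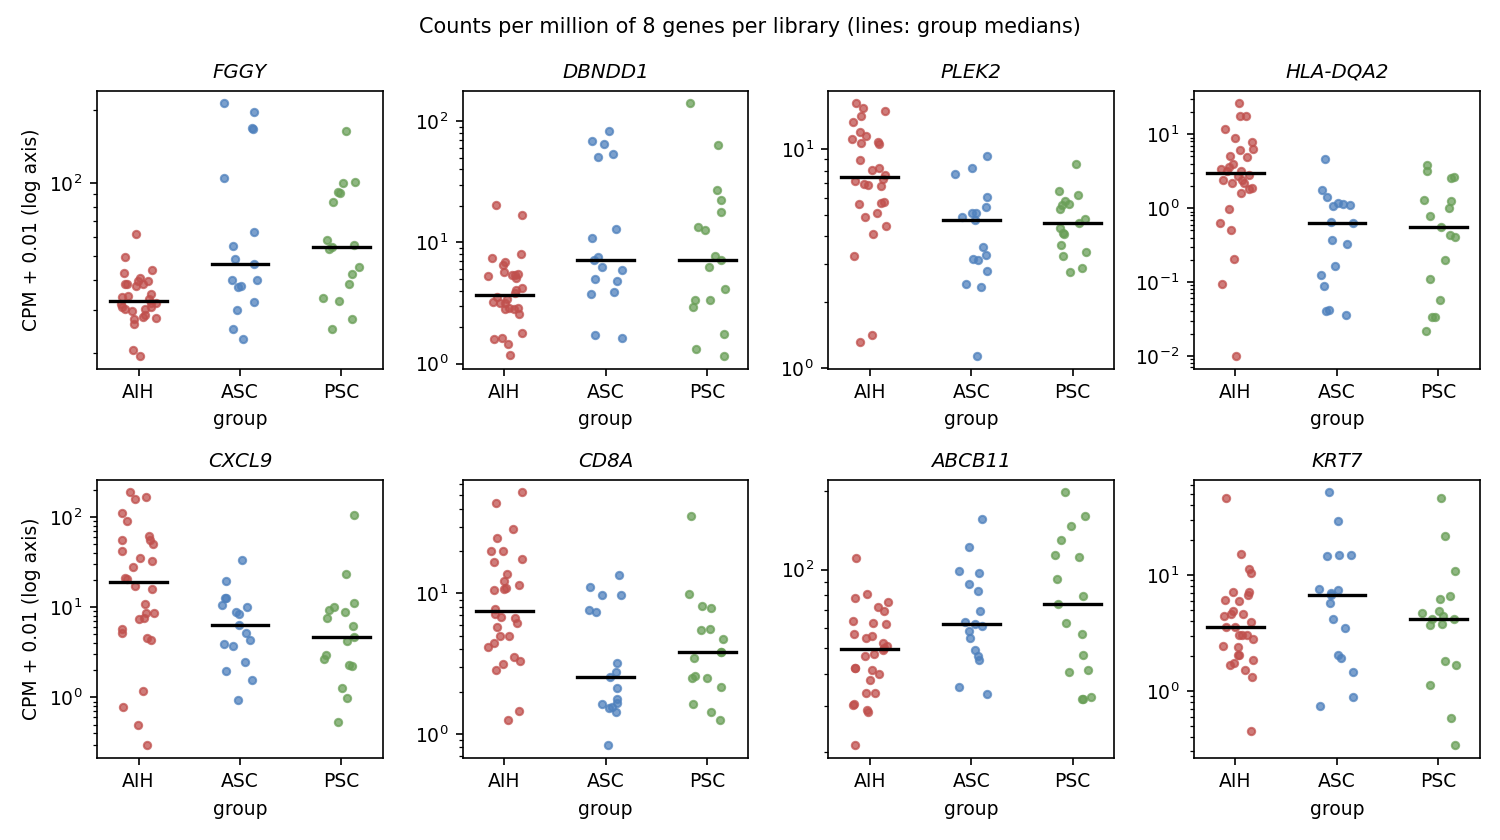
CPM (log axis, 0.01 added) of 8 genes in each of 30 AIH, 17 ASC and 17 PSC libraries, with a line at each group's median. The AIH median of FGGY, 32.9 CPM, lies below 27 of the 34 PSC and ASC libraries, and that of HLA-DQA2, 2.97 CPM, lies above 31 of them.

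Other called genes lost the call in some fits without 1 library. ACSM1, a mitochondrial medium-chain acyl-CoA synthetase, fell by 1.73 ± 0.36 (adjusted p = 0.0116, lower in 29 of 34 libraries), and the value was -0.87 and not called without 1 AIH library. The interferon-induced chemokine CXCL11 fell by 1.61 ± 0.38 (adjusted p = 0.0480, lower in 27 of 34) and stayed called in 23 of the 64 fits that left out 1 library, where its value was -1.46 at the least. It was not called with the run as a factor (-1.63 ± 0.43, adjusted p = 0.204) or with the leukocyte covariate, where its value shrank to -0.64 ± 0.28 (adjusted p = 0.716). The orphan nuclear receptor NR4A2 fell by 1.30 ± 0.31 (adjusted p = 0.0477, lower in 30 of 34) and stayed called in 24 of 64, with -0.64 at the least. TFF3, a mucosal trefoil peptide, fell by 2.88 ± 0.60 (adjusted p = 0.0121, lower in 21 of 34), with 75.8% of its CPM in 1 AIH library, and the value was -0.54 and not called without it. With the run as a factor ACSM1 was at -1.40 ± 0.38, NR4A2 at -0.90 ± 0.34 and TFF3 at -1.34 ± 0.60 (adjusted p = 0.212, 0.412 and 0.540), none of them called. The acute phase genes SAA1 and SAA2 rose by 3.26 ± 0.65 and 3.51 ± 0.73 (adjusted p = 0.0114 and 0.0116, higher in 21 and 20 of 34 libraries). With the run as a factor they were at 1.45 ± 0.61 and 1.42 ± 0.69 (adjusted p = 0.497 and 0.588). Without 1 ASC library their values were 1.42 and 1.31, and neither was called. The same library held 90.6% of the CPM of KRT5, a keratin of squamous epithelium (4.48 ± 0.93, adjusted p = 0.0116, higher in 18 of 34). It held 83.3% of that of S100A2 (3.73 ± 0.81, adjusted p = 0.0169, higher in 21 of 34) and 65.7% of that of PAPPA (2.72 ± 0.59, adjusted p = 0.0169, higher in 17 of 34). It held 57.5% of that of ADAM12 (2.33 ± 0.47, adjusted p = 0.0114, higher in 17 of 34). Without it S100A2 was at 0.43, PAPPA at 0.60 and ADAM12 at 0.63, none of them called, and KRT5 no longer had enough counts to be tested.

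T cell genes lay lower in PSC and ASC together than in AIH. All 20 members of the T cell list had a negative log2 fold change, with a median of -0.72. When adjusted over the list alone 16 fell, against 0 over all genes tested. Among them were the costimulatory receptor ICOS (-1.31 ± 0.37, lower in 31 of 34 libraries) and CD8A (-1.11 ± 0.30, adjusted p = 0.114 over all genes, lower in 25 of 34). The list passed camera at the preset correlation (adjusted p = 2.06e-19), and not otherwise (adjusted p = 0.186 with an estimated correlation). The list mean differed by -0.64 ± 0.23 log2 (permutation p = 0.00721, adjusted p = 0.126 over 42 lists), and by -0.35, -0.29, -1.03 and -0.59 within the 4 runs. The pan-leukocyte mean moved with it, 0.34 lower on the log2 scale, and with that mean in the model the difference was -0.25 ± 0.11.

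Genes induced by interferon gamma were lower as well. Of 21 tested members 20 had a negative log2 fold change, and the median was -0.53. When adjusted over the list alone 16 fell, against 1 over all genes tested (CXCL11). The T cell attracting chemokine CXCL9 differed by -1.83 ± 0.45 (adjusted p = 0.0613, lower in 30 of 34 libraries), and the guanylate-binding proteins GBP5 and GBP1 by -1.20 ± 0.29 and -0.72 ± 0.18 (adjusted p = 0.0523 and 0.0626, lower in 28 and 29 of 34). The list passed camera at the preset correlation (adjusted p = 1.52e-19; adjusted p = 0.186 with an estimated correlation). The list mean differed by -0.54 ± 0.20 (permutation p = 0.00611, adjusted p = 0.126), and by 0.43, -0.63, -0.96 and -0.49 within the runs. The run 1 value had an SE of 0.47 with 4 AIH libraries, so the direction in run 1 is not settled. With the pan-leukocyte mean in the model it was -0.22 ± 0.10.

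The antigen-presenting HLA class II list shifted in the same direction. All 12 members were negative with a median of -0.62, and 10 fell when adjusted over the list alone, against 0 over all genes. HLA-DRA, the invariant partner of the DR molecule, differed by -0.84 ± 0.23 (lower in 28 of 34 libraries), HLA-DOB by -1.16 ± 0.31 and HLA-DPA1 by -0.68 ± 0.21. Its adjusted p was 7.32e-13 at the preset correlation and 0.186 with an estimated correlation. The list mean differed by -0.59 ± 0.22 (permutation p = 0.00897, adjusted p = 0.126), with within-run values of 0.24, -0.45, -1.09 and -0.45, and was -0.20 ± 0.08 with the pan-leukocyte mean in the model. Camera with an estimated correlation and fry called 0 of 42 lists in this comparison, with 5 at an unadjusted p under 0.05 by either test, and the permutation of list means also called 0, with 5 at an unadjusted p under 0.05.

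**Figure D2:**
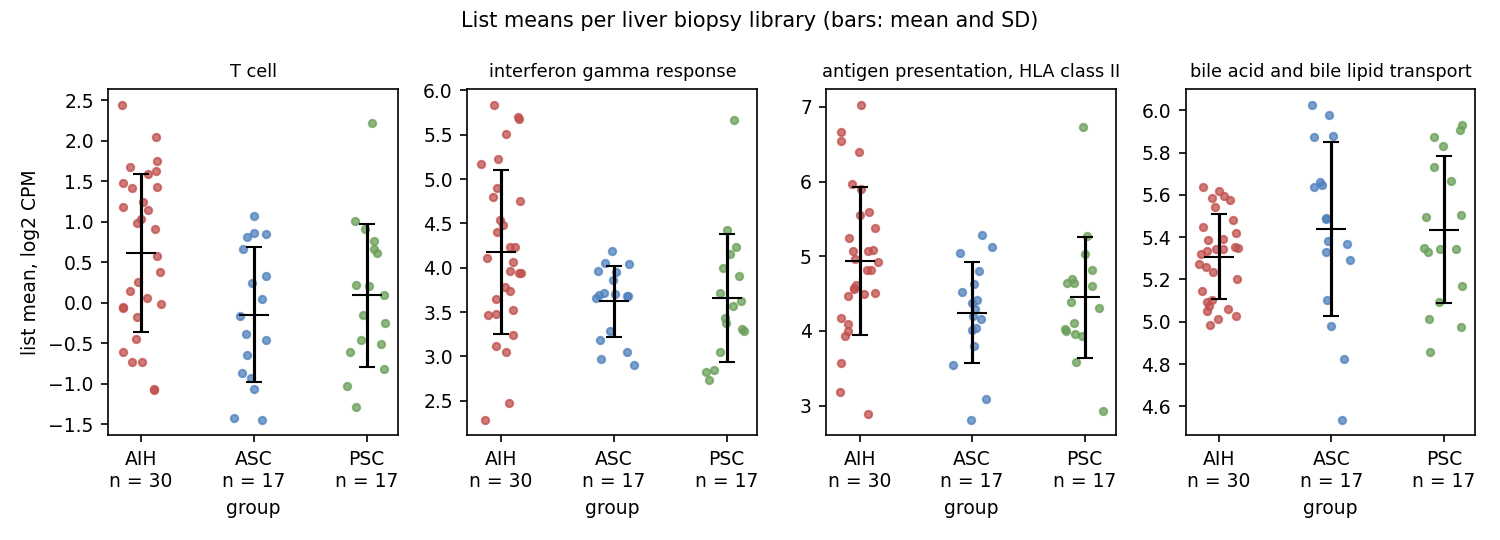
Mean log2 CPM of 4 gene lists in each library (points) with the group mean and SD (bars), for 30 AIH, 17 ASC and 17 PSC libraries. Against AIH, the mean of PSC and ASC together differs by -0.64 for T cell, -0.54 for interferon gamma response, -0.59 for HLA class II and 0.13 for bile acid and bile lipid transport genes, with wide overlap between the groups in all 4.

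Lists of T cell subsets held genes that moved in either direction. In the regulatory and checkpoint list of 17 tested genes, 7 fell and 1 rose when adjusted over the list alone, against 0 over all genes. The inhibitory receptors PDCD1 (-1.49 ± 0.37), CTLA4 (-1.34 ± 0.40) and TIGIT (-0.92 ± 0.29) were among the 7, and FOXP3, the transcription factor of regulatory T cells, was the member that rose, at 1.31 ± 0.40 (higher in 22 of 34 libraries). The medians of FOXP3, 5.38 and 3.33 CPM, lay above those of CTLA4, 0.158 and 0.594 CPM. Whether the FOXP3 counts come from T cells was not tested. In the cytotoxic T and NK list 7 of 20 genes fell, among them CD8B (-1.27 ± 0.32) and the granzyme GZMK (-0.67 ± 0.24), while the adhesion molecule NCAM1 rose (0.85 ± 0.21, higher in 27 of 34), again adjusted over the list alone, against 0 over all genes. The medians of NCAM1 were 3.92 and 2.15 CPM, against 0.44 and 1.3 CPM for CD8B, and the cells that express NCAM1 here were not determined. Both lists passed camera at the preset correlation only (adjusted p = 0.395 and 0.564 with an estimated correlation). With the pan-leukocyte mean in the model the list means differed by -0.10 ± 0.09 and -0.04 ± 0.12, against -0.41 and -0.37 without it.

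Plasma cell genes, the antibody-secreting compartment, were negative in 21 of 22 members with a median of -0.67. The surface receptor SLAMF7 (-1.10 ± 0.30) and the immunoglobulin A heavy chain IGHA1 (-1.44 ± 0.48) fell when adjusted over the list alone, against 0 over all genes, and IGHG1 differed by -0.82 ± 0.49 (adjusted p = 0.656, lower in 20 of 34). The list reached an adjusted p of 1.01e-08 at the preset correlation (adjusted p = 0.411 with an estimated correlation), and its mean differed by -0.62 ± 0.30 (permutation p = 0.0440, adjusted p = 0.370), with -0.49, -0.26, -1.23 and -0.66 within runs. With the pan-leukocyte mean in the model it differed by -0.22 ± 0.22 (p = 0.330). IGHA1 depended on 1 library, without which its value was -0.68.

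Few hepatocyte or bile duct genes passed the test. APOA1, the main protein of high-density lipoprotein, fell by 0.53 ± 0.14 when adjusted over its list of 20 hepatocyte plasma proteins alone (adjusted p = 0.0784 over all genes, medians 6904 and 10030 CPM, lower in 32 of 34 libraries), and differed by -0.12, -0.04, -0.60 and -0.53 within the runs. No other member passed, and the list was not shifted (median -0.02, camera adjusted p = 0.266). The bile acid and bile lipid transport list was positive in 17 of 20 members with a median of 0.14. Its only member past the threshold when adjusted over the list alone, against 0 over all genes, was ABCB11, the canalicular bile salt export pump, which rose by 0.57 ± 0.17 (medians 62.7 and 49.6 CPM, higher in 23 of 34 libraries). The list passed camera at the preset correlation only (adjusted p = 0.564 with an estimated correlation), and its mean differed by 0.13 ± 0.07 (permutation p = 0.0926), with 0.00, 0.27, 0.17 and -0.02 within runs. SLC51B, the basolateral bile acid exporter subunit, differed by 0.98 ± 0.55 (adjusted p = 0.627, higher in 21 of 34). CYP7A1, the rate-limiting enzyme of bile acid synthesis, differed by 0.14 ± 0.50 (adjusted p = 0.962, higher in 14 of 34) and ALB by -0.15 ± 0.13 (adjusted p = 0.793, lower in 22 of 34). In the cholangiocyte list the median was 0.15 and the mean -0.03, opposite in sign, and camera gave an adjusted p of 0.601; 1 member, TFF3, fell over all genes and over the list alone. The bile duct keratins KRT7 and KRT19 differed by 0.44 ± 0.36 and -0.33 ± 0.44 (adjusted p = 0.778 and 0.875, higher in 23 and 18 of 34). COL1A1 differed by 0.39 ± 0.28 (adjusted p = 0.727, higher in 19 of 34), and the fibrillar collagen list was not shifted (adjusted p = 0.0594).

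**Figure D3:**
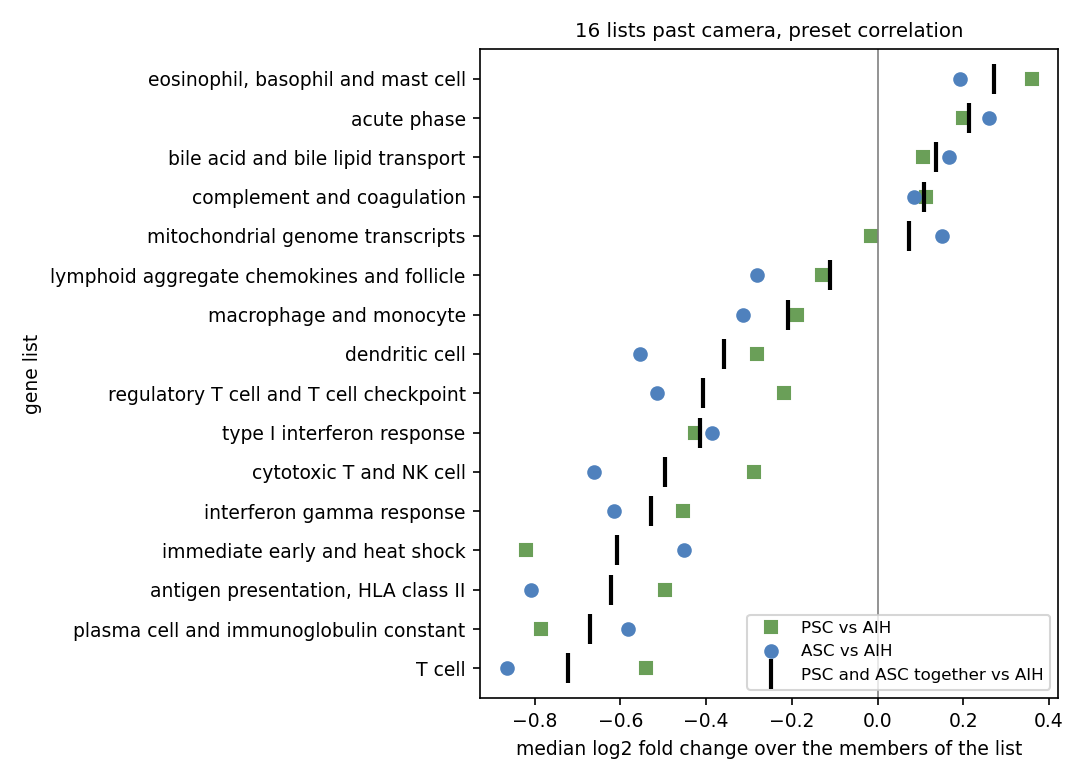
Median log2 fold change over the members of each of the 16 lists that passed camera at the preset correlation in PSC and ASC together against AIH (bars), with the same medians for PSC against AIH (squares) and ASC against AIH (circles). The T cell list lies at -0.72, -0.54 and -0.87 in that order, and none of the 16 passed with an estimated correlation.

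Of the 42 lists, 16 passed camera at the preset correlation, 5 shifted up and 11 down, and 8 of the 16 kept their shift with the leukocyte covariate. Among the others lower, the immediate early and heat shock list (median -0.61) had 6 of 18 genes that fell when adjusted over the list alone, against 0 over all genes, among them EGR3 at -1.35 ± 0.37, and HSPA1B at -1.61 ± 0.40, or -0.68 without 1 library (adjusted p of the list = 0.842 with an estimated correlation). Its list mean differed by only -0.24 ± 0.26 (permutation p = 0.364, adjusted p = 0.828), with 0.88, -0.17, -0.82 and -0.15 within runs. In the type I interferon list (median -0.41) 7 of 21 fell when adjusted over the list alone, against 0 over all genes, among them IFI27 at -1.11 ± 0.28 and OAS2 at -0.83 ± 0.26 (adjusted p = 0.858 with an estimated correlation). Its list mean differed by only -0.17 ± 0.20 (permutation p = 0.407, adjusted p = 0.828), with 0.58, -0.90, -0.35 and 0.18 within runs, so the direction of neither list held in all runs. The acute phase list (median 0.21, 18 of 20 positive) held SAA1 and SAA2, which passed over all genes and when adjusted over the list alone, and CRP at 1.18 ± 0.59 (adjusted p = 0.573); its adjusted p was 0.816 with an estimated correlation, and its mean differed by 0.26 ± 0.18 (permutation p = 0.160, adjusted p = 0.561), with 1.35, 0.07, -0.41 and 0.53 within runs.

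PSC alone was compared with AIH to separate it from ASC. The interferon-induced chemokines CXCL9, CXCL11 and CXCL10 differed by -1.59 ± 0.58, -1.42 ± 0.49 and -1.34 ± 0.52 (n = 17 and 30, adjusted p = 0.657, 0.629 and 0.658, lower in 15, 12 and 13 of 17 libraries). ABCB11 differed by 0.68 ± 0.20 (adjusted p = 0.449, higher in 11 of 17) and rose when adjusted over its list alone. In the immediate early and heat shock list 3 of 18 genes fell when adjusted over the list alone, against 0 over all genes: HSPA1B (-1.99 ± 0.52, lower in 12 of 17), NR4A1 (-2.35 ± 0.71) and HSPA1A (-1.12 ± 0.35, lower in 13 of 17). NR4A1 was lower in 9 of 17 libraries. Without 1 library the values of the 3 genes came to -1.06, -0.88 and -0.61 at the least. KRT7 (0.22 ± 0.44), KRT19 (-0.57 ± 0.55), ALB (-0.09 ± 0.16), CYP7A1 (0.01 ± 0.61), SLC51B (1.18 ± 0.64), COL1A1 (0.43 ± 0.33), CD8A (-0.91 ± 0.38) and IGHG1 (-1.19 ± 0.63) did not pass (adjusted p = 0.700 or more).

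No gene of 20300 was called by edgeR in PSC against AIH: the smallest adjusted p was 0.215, and 1399 genes lay at an unadjusted p under 0.05. DESeq2 called 9 and limma voom 4. Within the 4 runs edgeR called 0, 0, 2 and 0, with 2425, 1055, 2066 and 510 at an unadjusted p under 0.05. Camera at the preset correlation shifted 15 of 42 lists, 4 up and 11 down. The T cell list (20 of 20 negative, median -0.54), the interferon gamma list (21 of 22 negative, median -0.45) and the HLA class II list (12 of 12 negative, median -0.50) each had 0 members past the threshold when adjusted over the list alone and an adjusted p of 0.711 with an estimated correlation. The proliferation list was negative in 20 of 20 members (median -0.52, adjusted p = 0.833 with an estimated correlation), and the eosinophil, basophil and mast cell list was positive in 13 of 17 (median 0.36, adjusted p = 0.711 with an estimated correlation). Camera with an estimated correlation and fry called 0 lists, each with 2 at an unadjusted p under 0.05, and the permutation of list means called 0, with 1.

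In ASC against AIH the interferon-inducible genes GBP5 and GBP1 fell by 1.55 ± 0.37 and 0.93 ± 0.22 (n = 17 and 30, adjusted p = 0.0429 and 0.0467). GBP1 was lower in 17 of 17 ASC libraries, and GBP5 in 15 of 17. They kept their calls in 39 (GBP5) and 32 (GBP1) of the 64 fits without 1 library, with values of -1.43 and -0.86 at the least. With the run as a factor 0 genes were called in this comparison (smallest adjusted p = 0.0802, 1733 at an unadjusted p under 0.05). GBP5 was then at -1.45 ± 0.38 and GBP1 at -0.94 ± 0.23 (adjusted p = 0.233 and 0.204), so their folds were kept and their adjusted p rose. Their unadjusted edgeR p values were 0.000362 and 0.000131, against 7.4e-05 and 8.28e-05 without the run. With the leukocyte covariate the values shrank to -0.69 ± 0.20 and -0.47 ± 0.15 (adjusted p = 0.325 and 0.358). Within runs 1, 3 and 4 GBP5 differed by -0.69, -2.26 and -1.20 and GBP1 by -0.04, -1.46 and -0.93. Run 2 holds 1 ASC library and gives no value. CYP19A1, the aromatase of estrogen synthesis (5.64 ± 0.99, adjusted p = 0.000399, higher in 9 of 17), KRT5 (5.45 ± 0.91, adjusted p = 0.000378, higher in 8 of 17), S100A2 (4.64 ± 0.81, adjusted p = 0.000399, higher in 13 of 17) and SAA2 (4.35 ± 0.75, adjusted p = 0.000399, higher in 11 of 17) passed on the strength of 1 ASC library, without which they were at -0.65, -0.13, -0.16 and 1.14, and none was called. The metallothionein gene MT1B fell by 6.02 ± 1.36 (adjusted p = 0.0236, lower in 7 of 17), with 91.8% of its CPM in 1 AIH library, and the value was -1.85 and not called without it.

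The T cell, interferon gamma and HLA class II lists lay lower in ASC than in AIH. In the T cell list 20 of 20 members were negative (median -0.87), and 17 fell when adjusted over the list alone. By the same adjustment 16 of 22 fell in the interferon gamma list (median -0.61) and 10 of 12 in the HLA class II list (median -0.81). Over all genes tested the 3 counts were 0, 2 and 0. ICOS (-1.87 ± 0.47, adjusted p = 0.0827) was lower in 17 of 17 libraries, HLA-DPA1 differed by -0.83 ± 0.27, and CXCL9 by -2.13 ± 0.59 (adjusted p = 0.167, lower in 15 of 17). The regulatory and checkpoint list had 9 genes lower and 1 higher when adjusted over the list alone, and the cytotoxic T and NK list 10 and 1, against 0 over all genes. All 5 lists passed camera at the preset correlation, and with an estimated correlation their adjusted p values were 0.177, 0.177, 0.177, 0.237 and 0.407. CD8A (-1.35 ± 0.39), KRT7 (0.63 ± 0.43), KRT19 (-0.11 ± 0.54), ALB (-0.21 ± 0.16), CYP7A1 (0.26 ± 0.60), ABCB11 (0.45 ± 0.20), SLC51B (0.76 ± 0.65), COL1A1 (0.36 ± 0.33) and IGHG1 (-0.52 ± 0.61) did not pass over all genes (adjusted p = 0.210 or more).

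Of 20300 genes 38 were called in ASC against AIH, 32 higher and 6 lower, with 1476 at an unadjusted p under 0.05. DESeq2 called 33, 12 higher and 21 lower, 13 of them shared with edgeR, and limma voom called 1. Without 1 ASC library the count was 13, and within runs 1, 3 and 4 it was 0, 8 and 0, with 1089, 1939 and 1250 at an unadjusted p under 0.05. Camera at the preset correlation shifted 17 lists, 4 up and 13 down. With the leukocyte covariate 7 shifted up and 6 down, and 8 of the 17 kept their shift. With an estimated correlation and with fry 0 passed, each with 5 at an unadjusted p under 0.05, and the permutation of list means called 0, with 4.

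PSC was compared with ASC directly. SEMA3B, a secreted semaphorin (chromosome 3, 50260226 to 50277546), was lower in PSC by a log2 fold change of -2.36 ± 0.48 (n = 17 and 17, adjusted p = 0.0299, medians 4.21 and 6.99 CPM, lower in 14 of 17 libraries). COL7A1, the anchoring fibril collagen (chromosome 3, 48564073 to 48595329), was lower by -2.31 ± 0.48 (adjusted p = 0.0420, medians 1.93 and 2.36 CPM, lower in 12 of 17). The fold of each rested on 1 ASC library, a different one for each gene: without it SEMA3B differed by -0.57 ± 0.28 and COL7A1 by -0.21 ± 0.24, and neither was called. The call ended in 11 of the 64 fits without 1 library for SEMA3B and in 16 for COL7A1, that library included, and in the other fits the values were -2.32 and -2.27 at the least. Within runs 1, 3 and 4 SEMA3B differed by -1.32, -0.29 and -0.04, and COL7A1 by -0.67, -0.66 and -4.10. KRT7 (-0.41 ± 0.50), KRT19 (-0.45 ± 0.61), ALB (0.13 ± 0.18), CYP7A1 (-0.24 ± 0.69), ABCB11 (0.23 ± 0.23), SLC51B (0.42 ± 0.75), COL1A1 (0.07 ± 0.38), CXCL9 (0.54 ± 0.61), CD8A (0.44 ± 0.41) and IGHG1 (-0.67 ± 0.68) all had an adjusted p of 1.

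In all, 5 of 20300 genes were called in PSC against ASC, 0 higher and 5 lower, the other 3 being pseudogenes, and 760 lay at an unadjusted p under 0.05, where 1015 would be expected without any difference. The spread of that expected number was not determined. The number of called genes ran from 2 to 7 when 1 library was left out and was 0 within runs 1, 3 and 4, with 1087, 781 and 519 at an unadjusted p under 0.05. Proliferation genes were negative in 20 of 20 members, with a median of -0.50, for example MCM2 (-0.79 ± 0.35, lower in 14 of 17) and CCNB1 (-0.68 ± 0.38, lower in 14 of 17), and 0 fell when adjusted over the list alone. T cell genes were positive in 20 of 20 (median 0.33) and erythrocyte genes in 11 of 11 (median 1.44), with 0 past the threshold when adjusted over either list alone. These were 3 of the 15 lists past camera at the preset correlation, 8 up and 7 down. With an estimated correlation 0 of 42 lists passed (smallest adjusted p = 0.920), with 0 at an unadjusted p under 0.05, and fry and the permutation of list means gave 0 and 0 as well.

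The PSC and ASC comparisons share the AIH libraries, so their fold changes are related by construction. Across 20300 genes, which are not independent replicates, the log2 fold changes correlated at 0.457 with a covariance of 0.0632, and 69.0% had the same sign. Counts simulated with no group effect (20 simulations) gave a correlation of 0.365 (range 0.337 to 0.393), a covariance of 0.0288 and 61.8% of the same sign. Those counts were drawn independently for each gene, unlike real libraries, so their range may be too narrow to judge the observed values by. With the AIH libraries split into sets of 15, 1 for each comparison, the correlation was 0.112 (range -0.03 to 0.23), the covariance 0.0180 and the share of the same sign 55.0%.

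Correlations of list means across all 64 biopsies were computed for 3 pairs of lists. The cholangiocyte mean rose with the fibrillar collagen mean (Pearson r = 0.666, Spearman rho = 0.668, permutation p = 1e-05 for each, the smallest possible, adjusted p = 1.5e-05 over 3 pairs). The relation was 0.578 in AIH, 0.828 in ASC and 0.616 in PSC, and 0.355, 0.493, 0.675 and -0.05 within the 4 runs, so it did not hold in run 4. The cholangiocyte mean fell as the bile acid synthesis mean rose (r = -0.510, p = 3e-05; rho = -0.402, p = 0.00113, adjusted p = 3e-05 and 0.00113), with -0.352, -0.675 and -0.530 in AIH, ASC and PSC and -0.662, -0.588, -0.521 and -0.548 within the runs. The plasma cell mean rose with the interferon gamma mean (r = 0.597, rho = 0.610, p = 1e-05 for each, adjusted p = 1.5e-05), with 0.527, 0.611 and 0.732 in the groups and 0.293, 0.563, 0.707 and 0.899 within the runs. Without the 2 libraries farthest from the median of the first list the 3 values of r were 0.664, -0.459 and 0.670.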

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

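The tests of the library with placental transcripts and of calls that rest on 1 library were chosen after the results were seen, as were the fits without a single library and the permutation tests of list means with covariates, where only the bounds for the interferon gamma and HLA class II lists were set before their values were seen; the other tests below were planned. SEMA3B and COL7A1 stood out because the effect of PSC against AIH and that of ASC against AIH differed, as tested by the contrast of PSC with ASC. For SEMA3B the difference was -2.36 (adjusted p = 0.0299, lower in 14 of 17 PSC libraries), from -0.43 ± 0.41 in PSC and 1.92 ± 0.39 in ASC. For COL7A1 it was -2.31 (adjusted p = 0.0420, lower in 12 of 17), from 0.18 ± 0.41 in PSC and 2.49 ± 0.40 in ASC. Without 1 ASC library each, the values were -0.57 ± 0.28 for SEMA3B and -0.21 ± 0.24 for COL7A1, and neither was called. With the run as a factor they were -1.64 ± 0.43 and -1.57 ± 0.46 (adjusted p = 0.811 and 0.995).

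The interferon gamma and HLA class II list means were lower in PSC and ASC together than in AIH, by -0.54 ± 0.19 and -0.59 ± 0.22. Neither list passed adjustment over 42 lists in the permutation test of list means (adjusted p of 0.126 or more). Nor did either pass camera with an estimated correlation (adjusted p of 0.186 or more). The p values below are not adjusted over lists. With the pan-leukocyte mean in the model the differences shrank to -0.22 ± 0.10 (p = 0.0271) and -0.20 ± 0.08 (p = 0.0161). How closely that mean tracks the leukocyte share was not measured, so a remainder is possible even if the share is the whole cause. A lower leukocyte share may therefore account for part or all of the difference, and this fit cannot tell which. The interferon gamma difference stayed at -0.54 with the run as a factor (p = 0.00847) and at -0.54 with library size (p = 0.00640). This argues against library size, or an even shift between the runs as cut here, as the cause. Within the runs the difference was 0.43 ± 0.47, -0.63 ± 0.34, -0.96 ± 0.29 and -0.49 ± 0.54, and that of HLA class II was 0.24 ± 0.48 in run 1. A difference that depends on the run is therefore not excluded, and the runs are not known batches. The run at -0.96 includes a block of adjacent library numbers with PSC and ASC libraries only. That block has the lowest totals of the run, 77.15 to 85.11 M counts. The run factor cannot separate the block from disease. A difference between the diseases remains a hypothesis that was found and tested on the same data, and it stays open whether the leukocytes differ in number, type or activity. With the pan-leukocyte mean in the model the T cell list mean differed by -0.25 ± 0.11 (p = 0.0254), the plasma cell mean by -0.22 ± 0.22 (p = 0.330), the cytotoxic mean by -0.04 ± 0.12 (p = 0.743) and the regulatory and checkpoint mean by -0.10 ± 0.09 (p = 0.281).

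In 1 ASC library, transcripts of other tissues were abundant. Of 26 detected markers of placenta, stomach and squamous epithelium, 92.3% were highest in that library: 11 of 11 for placenta, 6 of 7 for stomach and 7 of 8 for squamous epithelium. The library was picked by the summed level of these same markers. Among them are KRT5, S100A2 and PAPPA, called only with that library in the fit, so part of the share was fixed by the choice. The summed level of the markers was 955 CPM (595 for placenta, 264 for squamous epithelium and 95.9 for stomach, with CSH1 the most abundant at 218 CPM), against 30.4 CPM in the next highest library and 1.27 CPM in the median library, while the ALB of the picked library was 34601 CPM against a median of 146340 CPM in the others. These values are consistent with reads from other tissues in that library, whose origin stays open, and no biological explanation was tested. Its SAA1 level, 48999 CPM against 3972 CPM in the next highest, has no tested explanation.

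Of 35 called genes in the pooled comparison, 80% lost the call when some 1 library was left out, and 7 kept it in all 64 fits. In 16 of the 28 that lost it the fold shrank by over 1.5 times in some fit, in 11 it did not, and 1 could not be tested in some fits. A call that ends with its fold kept says little about single libraries, so it stays open how many of the 35 rest on 1 library. Chance could not be excluded for the count of 35: 8 of 100 splits of the libraries gave as many, and the highest other split gave 192. Each of the 99 other splits called at least 2 genes, so the adjusted p of a single gene may be too small as well. For ASC against AIH, with 38 genes, 8 of 50 splits gave as many (highest other 171), and for PSC against ASC, with 5 genes, 17 of 50 (highest other 399). For PSC against AIH the real count was 0, which all 50 splits reach (highest other 495). The median of the other splits was 7, 2, 9 and 3 genes in the pooled comparison, PSC against AIH, ASC against AIH and PSC against ASC, so the high counts came from some splits only. Why some splits gave several times the real count was not tested. A structure of the samples and a few libraries with extreme values were not told apart. For shifted lists chance could not be excluded either: 44 of 100 splits gave 16 or more in the pooled comparison (highest other 28), 26 of 50 gave 15 or more in PSC against AIH (highest other 25), 32 of 50 gave 17 or more in ASC against AIH (highest other 26) and 27 of 50 gave 15 or more in PSC against ASC (highest other 26).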

How the results depend on the processing

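The fits without the library with placental transcripts, without the 6 libraries least like the others and without each library in turn, and the permutation of list means, were chosen after seeing the data; the other settings were planned. Each named gene counts once per comparison that names it. Of 24 named and called results, 135 of 298 values under the alternatives kept the direction without the call, 7 changed sign and 156 kept both. Of 108 named and uncalled results, 1320 of 1377 values stayed uncalled, in either direction, and 57 became called in the same direction. With RLE factors the pooled count was 32 and with upper-quartile factors 34. With a minimum absolute log2 fold change of 1 it was 28. The cause of the changes below was not tested, except where the filter or the libraries left out show it. No paired analysis was possible because the labels pair no samples.

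In the pooled comparison 35 genes became 66 with DESeq2, 63 with voom, 701 without a filter, 9 with the CPM filter, 4 with the run as a factor, 6 with the leukocyte covariate, 18 with the cholangiocyte covariate and 14 without the library with placental transcripts. The balance of 23 higher and 12 lower became 27 and 39 with DESeq2 (17 shared), 23 and 40 with voom (8 shared), 287 and 414 without a filter (35 shared), 6 and 8 without the library with placental transcripts (13 shared) and 11 and 21 without the 6 libraries (15 shared). In PSC against AIH 0 became 9 with DESeq2, 4 with voom, 699 without a filter and 2 with only the compared groups in the fit. In ASC against AIH 38, of which 32 were higher, became 33 with DESeq2 (12 higher and 21 lower, 13 shared), 1 with voom, 454 without a filter (155 higher and 299 lower, 38 shared), 9 with the CPM filter, 0 with the run as a factor (1733 at an unadjusted p under 0.05), 13 with the leukocyte covariate, 11 with the cholangiocyte covariate, 13 without the library with placental transcripts and 12 without the 6 libraries. In PSC against ASC 5 became 1 with DESeq2, 982 without a filter, 2 without the 6 libraries, and 0 with voom, with the CPM filter, with the run as a factor, with the cholangiocyte covariate and with only the compared groups in the fit (691, 297, 820, 767 and 579 at an unadjusted p under 0.05). Leaving out 1 library at a time gave 14 to 117, 0 to 0, 13 to 45 and 2 to 7 genes in these 4 comparisons. Of the genes called without a filter, 585 of 701, 661 of 699, 385 of 454 and 958 of 982 had too few counts to be tested with it.

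Of the lists shifted at the preset correlation, 0 passed with an estimated correlation, with fry and in the permutation of list means in each of the 4 comparisons, and with the leukocyte covariate 16 became 13, 15 became 12, 17 became 13 and 15 became 9, in the order pooled, PSC against AIH, ASC against AIH and PSC against ASC. Of the shifted lists 8, 9, 8 and 7 kept their shift there, and in ASC against AIH 4 up and 13 down became 7 up and 6 down. With the AIH libraries split, the correlation of the PSC and ASC fold changes was 0.112 and their covariance 0.0180. The log2 fold change of CYP19A1 in ASC against AIH was -0.74 with DESeq2, -0.65 without the library with placental transcripts and -0.53 without the 6 libraries, that of KRT5 was -0.21 with voom and -0.13 without that library and -0.072 without the 6, and that of S100A2 was -0.16 without the library with placental transcripts. The smallest library held 40.16 M counts. On simulated counts, drawn independently for each gene, the pooled edgeR test called 80% of genes changed 2-fold.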

Other observations

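The gene pairs below were picked from a wider search after its values were seen. FGGY and DBNDD1 were each correlated with 11797 genes of mean log2 CPM over 1, in PSC and ASC, in AIH and in all 64 libraries, 70782 relations in total. FGGY was also set against 10 genes picked by hand, DBNDD1, SLC51B, SLC51A, ABCB11, ABCB4, NR0B2, CYP7A1, CYP8B1, KRT7 and PLEK2. The adjustment over 3 pairs below does not cover that search, so the pattern is a hypothesis for other samples. FGGY and DBNDD1, which rose in PSC and ASC together, varied widely among the 34 PSC and ASC libraries and did so in step. Across these libraries their log2 CPM correlated at r = 0.774 (permutation p = 1e-05, the smallest possible) and rho = 0.659 (p = 7e-05), with adjusted p = 1.5e-05 and 0.000105 over 3 pairs. Over the whole search r had an adjusted p of 5.99e-05 (t distribution), DBNDD1 ranked 7 by absolute r with FGGY, and 414 genes passed an adjusted p of 0.05 with FGGY. The value was 0.775 in ASC (n = 17), 0.808 in PSC (n = 17), and 0.869, 0.785 and 0.880 within runs 1, 3 and 4; run 2 holds too few of these libraries. In AIH r was -0.323 (p = 0.0837, n = 30), and the difference of 1.10 between the values of r had an adjusted permutation p of 3e-05 over 3 pairs and ranked 3 among the 11797 genes set against FGGY. SLC51B, the bile acid exporter subunit that is known to rise in cholestasis, varied with DBNDD1 (r = 0.783, rho = 0.783, p = 1e-05 for each, adjusted p = 1.5e-05 and 3e-05) and with FGGY (r = 0.538, p = 0.00103; rho = 0.489, p = 0.00336, adjusted p equal to these). In ASC and PSC the DBNDD1 and SLC51B values were 0.764 and 0.798, and the FGGY and SLC51B values 0.411 (p = 0.0998) and 0.718 (p = 0.00109), so that pair did not pass in ASC. In AIH the values of the 2 pairs were 0.274 and -0.345. Within runs 1, 3 and 4, in PSC and ASC libraries, the DBNDD1 and SLC51B values were 0.841, 0.786 and -0.311, and the FGGY and SLC51B values 0.611, 0.727 and -0.173, so the relation to SLC51B did not hold in run 4. Without the 2 libraries farthest from the median of the first gene the 3 pairs gave 0.732, 0.746 and 0.510, in the order FGGY and DBNDD1, DBNDD1 and SLC51B, FGGY and SLC51B. SLC51B lies below the mean log2 CPM of 1 and was not in the search over all genes. The other genes picked by hand gave r with FGGY in PSC and ASC of 0.654 (SLC51A, adjusted p = 0.00339 over the search), 0.513 (ABCB4, 0.0422), 0.484 (ABCB11, 0.0602), 0.295 (KRT7, 0.318), 0.183 (CYP8B1, 0.578), 0.118 (NR0B2, 0.744), -0.236 (CYP7A1, 0.449) and -0.317 (PLEK2, 0.276). In AIH r with FGGY was 0.131 for SLC51A, -0.227 for ABCB4 and 0.503 for ABCB11, so the ABCB11 value was not particular to PSC and ASC. Over the search 967 genes passed with FGGY in AIH.

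Further lists held genes that passed when adjusted over the list alone in the pooled comparison. The matrix protease list had 3 higher and 1 lower, of which ADAM12 also passed over all genes, though not without 1 ASC library. The list of mesothelium, fat, muscle and skin genes had 1 higher, KRT5, and 3 lower. KRT5 also passed over all genes, with 90.6% of its CPM in 1 ASC library. Neither list was shifted (camera adjusted p = 0.601 and 0.490). In the matrix protease list MMP7, a matrix protease made by bile duct epithelium, rose by 1.28 ± 0.46 (medians 1.78 and 0.708 CPM, higher in 20 of 34 libraries), and differed by 0.97 to 1.99 in runs 1 to 3 and by -1.47 in run 4. The dendritic cell list shifted down at the preset correlation (median -0.36, 12 of 14 negative, adjusted p = 0.534 with an estimated correlation). In it CLEC10A, a lectin of conventional dendritic cells, fell by 0.51 ± 0.16 (medians 6.5 and 9.9 CPM, lower in 29 of 34) and CADM1 rose by 0.33 ± 0.12 (medians 98.8 and 91.7 CPM, higher in 23 of 34). Whether the CADM1 counts come from dendritic cells was not tested. MMP7, CLEC10A and CADM1 were not called over all genes. The macrophage list was negative in 17 of 22 members (median -0.21, adjusted p = 0.858 with an estimated correlation) and the lymphoid aggregate list in 12 of 18 (median -0.11, adjusted p = 0.564). The eosinophil, basophil and mast cell list was positive in 13 of 17 (median 0.27, adjusted p = 0.686), the complement and coagulation list in 19 of 24 (median 0.11, adjusted p = 0.858) and the mitochondrial transcripts in 12 of 13 (median 0.07, adjusted p = 0.825), with no member past the threshold when adjusted over any of these 5 lists alone. Within the runs the mitochondrial list mean differed by -0.02 ± 0.22, 0.58 ± 0.23, 0.55 ± 0.16 and -0.29 ± 0.51. Proliferation genes were negative in 20 of 20 members in PSC against AIH and had a median of -0.04 in ASC against AIH, where the list was not shifted (camera adjusted p = 0.543, upward, opposite in sign to the median).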
